A study of Mus musculus with 20 samples.

How the data were processed

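Enhancer transcription was measured in 20 nAnT-iCAGE libraries from C57BL/6 bone marrow-derived macrophages in 10 groups of 2: unstimulated cells at 0 h, and IFN-γ, CpG or both at 3, 9 and 15 h. Groups and replicate numbers were taken from the sample titles and characteristics. Per the labels' protocols, marrow cells were differentiated with M-CSF, total RNA was extracted with TRIzol, and libraries were made without amplification. The protocols also describe an IL-4 and IL-10 polarization step and a stimulation of a different length from the times on the samples; whether these steps and the doses in that text apply to the CAGE samples is not stated, so they are not used here. Per the submitters' processing notes, the tools were FastQC 0.11.5, Trimmomatic 0.38, BWA 0.7.10 and HISAT2 2.1.0 and the build was mm39; the enhancer caller and its settings are not given in the sources used here.

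The authors deposited raw tag counts for 11222 enhancers in each library and a second table of the same enhancers that its name calls TPM. Per the file headers and values, the deposited values of this second table are RPM, relative to the tags of the whole library: the raw count divided by it gave a single library total for every enhancer with a tag in a library (12776280 to 13855472 tags). Enhancers thus held 0.0991% to 0.220% of a library. Each enhancer had at least 2 tags over the 20 libraries. All libraries and columns could be mapped to samples.

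Raw counts were tested with edgeR 4.0.16 (quasi-likelihood F-test, robust, two-sided) in R 4.3.3, with 1 coefficient per group over all 20 libraries, which left 10 residual degrees of freedom, and TMM factors on the enhancer tags. Enhancers were kept by filterByExpr with a minimum count of 5 and a minimum total of 15, which left 2792, holding 59.0% to 64.7% of enhancer tags. An enhancer was called at a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 change was taken as its size divided by the square root of F. The 24 comparisons were each stimulus against unstimulated cells at each time, the 3 pairs of stimuli at each time, the departure from additivity of log2 responses at each time, and 15 h against 3 h for each stimulus. The design, the comparisons, the alternatives and the rule for named enhancers were fixed before the data were examined; the window test, the thinning, the comparison of each stimulus alone and on top of the other, the tests by whole-library totals on thinned libraries and of additivity, the count of enhancers without a tag in unstimulated cells, and the count of enhancers above or below both single stimuli were added later.

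Named enhancers were those with the largest log2 changes past the threshold, both libraries of a group beyond both of the other, and a mean of at least 5 tags: 5 rises and 3 falls for each comparison with unstimulated cells, 3 and 2 between stimuli, and 2 each way for the others; enhancers chosen otherwise are marked in the text. The rule also foresaw enhancers near chosen genes, gene list tests and motif tests. These were not run, because the annotation at hand is of GRCm38, an older build than mm39, and coordinates were not converted between builds; genes near the enhancers are therefore not analysed here. Whether the deposited starts count from 0 or 1 is not stated, and positions are printed as deposited.

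A fold against a group with no tag is given as a lower bound against a floor of 3 tags over the group. With 1 to 3 tags in a group the ratio of RPM is given with an exact 95% interval. Floors and intervals cover counting error only. The common biological coefficient of variation was 17.8%. On simulated data with the real means, library sizes and 2792 enhancers, the test recovered 90.0% of 8-fold rises, 50.0% of 4-fold rises, 2.00% of 2-fold rises and 12.0% of 4-fold falls for IFN-γ at 3 h against unstimulated cells, and 6.10% of its calls were false. Taking the replicate number as the tested term, where no effect is known, edgeR called 0 of 2792 enhancers (3.12% under an unadjusted p of 0.05) and DESeq2 0 (1.15%).

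Alternatives were RLE factors, DESeq2 1.42.0, whole-library totals, no filter, a stricter filter (minimum count 10, minimum total 30), the replicate number as a block, fits of the compared groups alone, limma 3.58.1 on log2 of the deposited RPM values plus 0.5 (or 0.1 or 2), and leaving out each library. The limma fits on RPM share the scaling to whole-library totals and are not a separate check of scaling. Set tests of the departure from additivity used camera from limma on voom values. Results were not corrected for the median log2 change of all tested enhancers, which was 0.23 to 0.32 for both stimuli against unstimulated cells with TMM and -0.30 to 0.40 over the 9 comparisons with unstimulated cells under whole-library totals.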

Results

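Capped RNA 5' ends were counted by nAnT-iCAGE, a form of cap analysis of gene expression without amplification, in macrophages grown from the bone marrow of C57BL/6 mice. The counted regions were the 11222 enhancers of the deposited table, so that a tag count is a reading of transcription at a region listed as an enhancer. Overlap of these regions with promoters or genes was not checked here. Cells were left unstimulated (0 h) or received interferon gamma (IFN-γ), the TLR9 agonist CpG oligodeoxynucleotide (CpG), or both, for 3, 9 or 15 h. Unstimulated here means without IFN-γ and CpG. The protocols also describe a polarization step with IL-4 and IL-10, and whether all these cells had passed through it is not stated. These 10 groups held 2 libraries each, which the series describes as biological replicates. Whole libraries held 12776280 to 13855472 tags, of which 12879 to 29794 lay in enhancers (0.0991% to 0.220%). Enhancer tags amounted to 1552 ± 58.0 RPM in unstimulated cells (mean ± SD, n = 2), 1905 ± 419 with both stimuli at 3 h and 1153 ± 229 with IFN-γ at 3 h; an exact permutation test of 2 libraries against 2 cannot give a p below 0.333. Of the 11222 enhancers, 2792 had enough tags to be tested, with a median of 3 tags per enhancer and library, and these are the enhancers meant below. Replicates correlated across enhancers at r = 0.628 to 0.784 on log values, and each pair differed by more than sampling noise (chi-square per degree of freedom 1.1 to 1.28). Enhancers are given by chromosome, start and end on mm39, in the coordinates of the deposited table; levels are in RPM, tags relative to the total of the whole library, as mean ± SD of 2 libraries. Genes near these enhancers were not assigned here. No untreated cells of 3, 9 or 15 h are among the samples, so that comparisons with unstimulated cells also contain any effect of time in culture.

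The first comparison asked which enhancers responded to IFN-γ alone. Rises included enhancers without a tag in unstimulated cells, which a ranking by fitted log2 change puts first. The enhancer at chr3:121164067-121164375 had no tag in either unstimulated library and reached 1.14 ± 0.525 RPM at 3 h, 2.93 ± 0.782 at 9 h and 2.45 ± 0.284 at 15 h. This is at least 14.2-fold, at least 29.6-fold and at least 27.8-fold higher against a floor of 3 tags over the unstimulated group (edgeR adjusted p = 4.81e-09, 2.48e-18 and 7.20e-17). A second one, chr15:74870658-74871129, went from 0 tags to 1.22 ± 0.308 RPM at 3 h and stood at 1.23 ± 0.0967 and 1.2 ± 0.222 at 9 and 15 h. In all, 293 enhancers changed at 3 h (212 higher, 81 lower), 543 at 9 h (359 higher, 184 lower) and 420 at 15 h (282 higher, 138 lower). Of 372 tested enhancers without a tag in unstimulated cells, 95, 167 and 141 were called higher at 3, 9 and 15 h and 57 at all 3 times, in comparisons that share the unstimulated libraries. Such enhancers passed the filter through stimulated groups and can only be called higher, so that the direction of these calls was fixed by the choice. Each of these counts was lower in some fits with 1 unstimulated or IFN-γ library left out, where a group rests on a single library.

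Other enhancers among the 5 with the steepest rises at one or more times were also without a tag in unstimulated cells. They were chr1:173879828-173879978 with 10 and 13 tags at 3 h (at least 10.9-fold higher, edgeR adjusted p = 2.66e-06) and chr10:117555820-117556219 with 12 and 22 tags at 9 h (at least 12.4-fold, 1.25e-07). To these belong chr11:21189605-21190141 with 20 and 10 tags at 9 h (at least 11.0-fold, 2.60e-07) and chr1:170845432-170845645 with 12 and 19 tags at 15 h (at least 13.3-fold, 3.66e-08). Enhancers chr19:11517556-11517878 and chr1:92996984-92997427 rose likewise, with 11 and 10 and 7 and 13 tags at 15 h. Falls were fewer than rises at each time with TMM factors. At 9 h the enhancer chr2:13409909-13410211 fell from 1.62 ± 0.552 to 0.0363 ± 0.0514 RPM, with 44 tags in unstimulated cells against 1, a ratio of 40.1-fold (95% counting interval 6.83 to 1620), edgeR adjusted p = 5.87e-07. At 15 h chr15:83058286-83058732 fell from 16 and 10 tags to none (at least 6.74-fold lower, edgeR adjusted p = 9.93e-05) and chr16:92195695-92195978 from 12 and 7 to none (at least 4.93-fold, 0.00111). At 3 h chr6:146014641-146015042 fell from 0.991 ± 0.0720 to 0.0378 ± 0.0534 RPM (edgeR adjusted p = 7.82e-04), a call that DESeq2 did not make.

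The share of rises depended on how libraries were scaled: with factors from the enhancer tags (TMM), 72.4%, 66.1% and 67.1% of the calls at 3, 9 and 15 h were rises, and with whole-library totals 42.0%, 60.3% and 49.5%. With limma on RPM falls outnumbered rises at 3 h (141 higher, 279 lower) and 15 h (238 higher, 288 lower). With 1 of the 4 libraries left out, 99 to 162 enhancers were called at 3 h, 228 to 369 at 9 h and 137 to 195 at 15 h, and DESeq2 called 88, 159 and 120.

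The same comparison for CpG asked which enhancers answered a TLR9 ligand. Fewer enhancers were called at 3 h than later: 43 enhancers changed at 3 h (33 higher, 10 lower), 195 at 9 h (125 higher, 70 lower) and 212 at 15 h (127 higher, 85 lower). The counts at 3 and 9 h were 68 and 132 with the stricter filter, 20 and 41 with DESeq2 and 111 and 287 with limma, so that the size of this difference depended on the setting. The enhancer chr19:10822778-10823211 had no tag in unstimulated cells and stood at 0.605 ± 0.116, 1.30 ± 0.260 and 1.51 ± 0.403 RPM at 3, 9 and 15 h, or at least 6.71-fold, at least 12.2-fold and at least 14.6-fold higher (edgeR adjusted p = 6.76e-04, 6.16e-08 and 4.35e-09). Its call at 3 h was lost without control replicate 1. Enhancer chr7:126752700-126752963 rose from 0 tags to 11 and 17 at 9 h (at least 9.74-fold, edgeR adjusted p = 9.17e-06) and chr2:117129364-117129727 to 12 and 13 at 9 h (at least 8.70-fold, 1.06e-05). At 15 h, chr2:77937049-77937442 rose to 12 and 12 tags (edgeR, at least 8.99-fold, 2.52e-05), chr5:65042388-65042734 to 12 and 8 (at least 7.49-fold, 1.59e-04) and chr4:62200596-62201074 to 11 and 6 (at least 6.37-fold, 5.80e-04). At chr13:113750503-113750811, 2 tags in unstimulated cells stood against 28 with CpG at 3 h, a ratio of 17.6-fold (95% counting interval 4.44 to 153), and this call was lost without control replicate 1.

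Among the falls with CpG, chr1:154935259-154935510 went from 1.58 ± 0.124 to 0.151 ± 0.00235 RPM at 3 h, a log2 change of -3.03 ± 0.63 (SE; edgeR adjusted p = 6.76e-04). Enhancer chr8:84930648-84930939 went from 1.25 ± 0.0785 to 0.112 ± 0.0529 at 9 h, with 34 tags against 3, a ratio of 10.9-fold (95% counting interval 3.42 to 55.3). Enhancer chr5:142804435-142804856 fell at 3 h, from 38 tags to 3, a ratio of 10.1-fold (95% counting interval 3.20 to 51.0), and was back at 1.32 ± 0.0927 RPM at 15 h against 1.39 ± 0.0283 in unstimulated cells; without CpG 3 h replicate 1 its call at 3 h was lost. Rises made up 76.7%, 64.1% and 59.9% of the calls at 3, 9 and 15 h, and 50.0% at 3 h with whole-library totals. With limma falls outnumbered rises at 3 h (37 higher, 74 lower) and 15 h (148 higher, 162 lower). Leaving out 1 library gave 11 to 22, 52 to 86 and 59 to 95 calls, a fit of the compared groups alone gave 78 at 3 h, and DESeq2 called 20, 41 and 46.

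Both stimuli together changed 764 enhancers at 3 h (514 higher, 250 lower), 624 at 9 h (393 higher, 231 lower) and 705 at 15 h (435 higher, 270 lower). The enhancer chr15:74870658-74871129 rose from 0 tags to 2.23 ± 0.0883 RPM at 3 h (at least 19.9-fold higher, edgeR adjusted p = 5.09e-13). Enhancer chr16:17285443-17285962 rose from 0 to 2.88 ± 0.633 at 9 h and 2.44 ± 0.525 at 15 h (at least 32.4-fold and at least 20.7-fold, 2.00e-18 and 1.94e-13). The steepest rises at 15 h joined enhancers named above for IFN-γ and for CpG: chr3:121164067-121164375 stood at 2.68 ± 0.484, chr19:10822778-10823211 at 1.90 ± 0.0745, chr2:117129364-117129727 at 1.90 ± 0.182 and chr5:65042388-65042734 at 1.72 ± 0.872 RPM, each from 0. The enhancer chr1:128518463-128519014 fell from 3.89 ± 0.598 to 0.0759 ± 2.84e-04 at 9 h, with 106 tags against 2, a ratio of 41.5-fold (95% counting interval 11.2 to 347), edgeR adjusted p = 5.74e-15.

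At 3 h, chr19:10256978-10257378 fell from 22 and 8 tags to none (at least 10.2-fold lower, edgeR adjusted p = 1.13e-06) and chr14:25473492-25474157 from 9 and 20 to none (at least 9.86-fold, 1.90e-06). At 9 h, chr5:120696843-120697231 fell from 12 and 13 tags to none (at least 6.52-fold lower, edgeR adjusted p = 8.12e-05). At 15 h, chr2:13409909-13410211 held 1 tag against 44, a ratio of 45.3-fold (95% counting interval 7.71 to 1829), and chr5:136487213-136487785 held 1 against 42, a ratio of 43.2-fold (95% counting interval 7.35 to 1748). Rises made up 67.3%, 63.0% and 61.7% of the calls at 3, 9 and 15 h, and 49.0% at 9 h with whole-library totals, where limma also called more falls (305 higher, 398 lower). Leaving out 1 library gave 382 to 510, 294 to 372 and 336 to 483 calls, and DESeq2 called 271, 211 and 233.

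**Figure D1:**
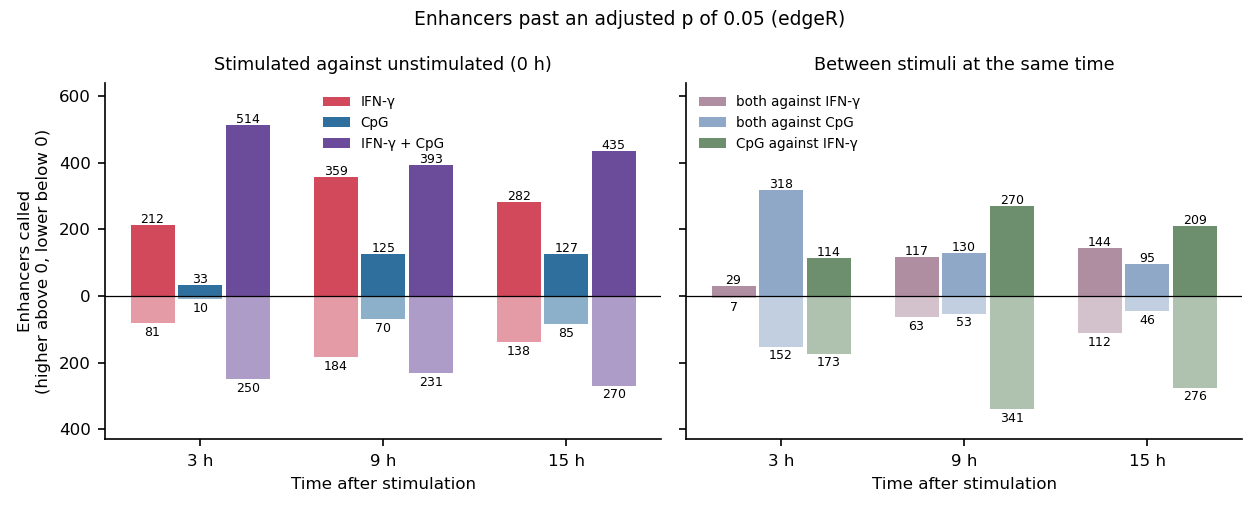
Number of enhancers past an edgeR adjusted p of 0.05 out of 2792 tested (TMM factors), higher above the zero line and lower below it. The left panel shows each stimulus against unstimulated cells at 3, 9 and 15 h, with 514 rises and 250 falls for both stimuli at 3 h against 33 and 10 for CpG; the right panel shows the stimuli against each other at the same time.

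Comparing both stimuli with IFN-γ at the same time shows what CpG added, with time in culture held equal. At 9 h 180 enhancers differed (117 higher, 63 lower) and at 15 h 256 (144 higher, 112 lower). Enhancer chr3:58424715-58425015 had no tag with IFN-γ at 9 or 15 h and 1.18 ± 0.38 and 1.38 ± 0.912 RPM with both stimuli (at least 12.0-fold and at least 9.07-fold higher, edgeR adjusted p = 1.19e-06 and 7.77e-06). Enhancer chr2:77937049-77937442 had no tag with IFN-γ at 15 h and 23 and 14 with both (at least 9.32-fold, 5.22e-06). In the other direction, the enhancer at chr17:27766195-27766562 was lower with both stimuli than with IFN-γ at 3 h, 0.552 ± 0.474 against 2.39 ± 1.21 RPM, a log2 difference of -2.57 ± 0.43 (SE; edgeR adjusted p = 4.36e-06).

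At 3 h, 36 enhancers differed between both stimuli and IFN-γ (29 higher, 7 lower), and this count depended on each single library. It was 1 without combination 3 h replicate 2 and 1 to 4 without any 1 of the 4 libraries. It was 1 with DESeq2, 4 with no filter on low counts, and 110 (106 higher, 4 lower) with whole-library totals. Rises did not outnumber falls at 3 h with DESeq2, with no filter, or with any 1 of the 4 libraries left out. Rises were 65.0% and 56.3% of the calls at 9 and 15 h, and 53.9% and 83.9% with whole-library totals. Falls outnumbered rises at 9 h with limma (122 higher, 156 lower), and at 15 h without IFN-γ replicate 1 (38 higher, 43 lower) or 2 (36 higher, 38 lower). At 9 and 15 h, leaving out 1 library gave 42 to 59 and 74 to 105 calls, and DESeq2 called 28 and 55.

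Comparing both stimuli with CpG at the same time shows what IFN-γ added. Here the early time point gave the most calls, 470 at 3 h (318 higher, 152 lower), against 183 at 9 h (130 higher, 53 lower) and 141 at 15 h (95 higher, 46 lower). Enhancer chr11:70366036-70366623 had no tag with CpG at 9 h and 1.1 ± 0.272 RPM with both stimuli (at least 11.8-fold higher, edgeR adjusted p = 7.76e-07). Enhancer chr16:17285443-17285962 had no tag with CpG at 15 h and 28 and 36 with both (at least 18.4-fold, 8.47e-12). Enhancer chr1:176651455-176651913 had none with CpG at 9 or 15 h and 0.948 ± 0.265 and 1.25 ± 0.00445 RPM with both (at least 10.2-fold and at least 9.51-fold, 6.45e-07 and 5.45e-07). Enhancer chr19:10256978-10257378 was lower with both stimuli at 3 h, with no tag against 12 and 7 (at least 8.13-fold lower, 4.69e-05). Rises were 67.7%, 71.0% and 67.4% of the calls at 3, 9 and 15 h, and 81.6%, 54.9% and 82.1% with whole-library totals. At 9 h limma called more falls (125 higher, 159 lower). Leaving out 1 library gave 161 to 275, 49 to 71 and 33 to 72 calls, and DESeq2 called 118, 56 and 36.

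The single stimuli differed from each other at 287 enhancers at 3 h (114 higher with CpG, 173 higher with IFN-γ), 611 at 9 h (270 and 341) and 485 at 15 h (209 and 276). The enhancer chr1:176651455-176651913 stood at 1.48 ± 0.160 RPM with IFN-γ at 9 h and had no tag with CpG (at least 14.4-fold lower with CpG, edgeR adjusted p = 2.71e-10). Enhancer chr11:58850818-58851268 stood at 1.62 ± 0.0654 with IFN-γ at 15 h and had none with CpG (at least 16.4-fold, 9.62e-10). Enhancer chr9:47556282-47556703 had 17 and 16 tags with IFN-γ at 9 h and none with CpG (at least 11.6-fold, 3.18e-07). The opposite held at 15 h for chr12:35783561-35783942, chr17:56268411-56268705 and chr5:90843879-90844435, which had no tag with IFN-γ and 1.05 ± 0.288, 1.01 ± 0.342 and 1.01 ± 0.0967 RPM with CpG. These are at least 7.87-fold, at least 7.58-fold and at least 7.58-fold higher, with adjusted p = 3.15e-05, 1.20e-05 and 4.45e-05 (edgeR). At 3 h chr6:113215477-113215828 was without a tag with CpG against 15 and 11 with IFN-γ, and chr7:140972595-140973198 was without a tag with IFN-γ against 11 and 11 with CpG. The differences are at least 9.77-fold lower and at least 6.51-fold higher with CpG, edgeR adjusted p = 9.44e-06 and 2.35e-04. The share of calls that were higher with CpG was 39.7%, 44.2% and 43.1%, and 48.0%, 48.7% and 56.2% with whole-library totals, so that the excess on the side of IFN-γ at 15 h turned round. It also turned round at 15 h without CpG replicate 1 or 2. With limma, which was run on RPM and so shares the whole-library scaling, it turned round at 15 h (328 higher, 270 lower) and 3 h (172 higher, 147 lower). Leaving out 1 library gave 97 to 123, 234 to 392 and 207 to 231 calls, and DESeq2 called 78, 180 and 137.

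Each stimulus could be read in 2 sets of libraries that share none: alone against unstimulated cells, and on top of the other stimulus at the same time. For IFN-γ at 3 h, 141 enhancers rose in both readings, where 24.1 would be shared by independent lists of that size, and at 9 and 15 h 81 and 52 did against 16.7 and 9.60. For CpG the shared rises were 2 at 3 h against 0.343, 42 at 9 h against 5.24 and 53 at 15 h against 6.55. The expected numbers give each enhancer the same chance of a call. Enhancers with more tags are called more easily, so that unrelated lists could share more than this. No enhancer was called in opposite directions in the 2 readings at any time, for either stimulus. With 1 library left out the shared rises at 3, 9 and 15 h were 57 to 110, 28 to 66 and 19 to 38 for IFN-γ and 0 to 3, 8 to 30 and 21 to 38 for CpG. DESeq2 gave 41, 32 and 23 for IFN-γ and 0, 7 and 14 for CpG. Across enhancers, which are not independent replicates, the log2 changes of the 2 readings correlated at r = 0.62, 0.56 and 0.52 for IFN-γ at 3, 9 and 15 h and at r = 0.33, 0.41 and 0.43 for CpG.

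**Figure D2:**
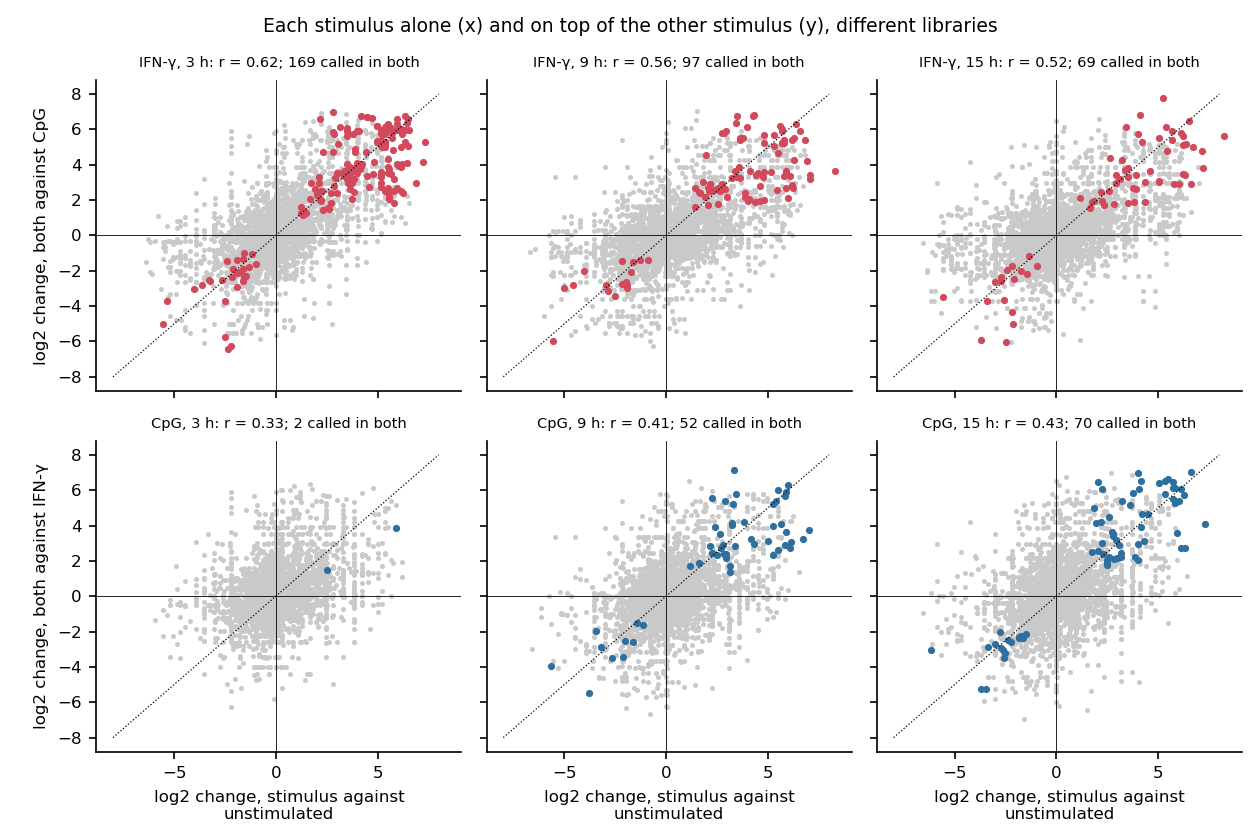
Log2 change of each of 2792 enhancers for a stimulus against unstimulated cells (x axis) and for both stimuli against the other stimulus alone (y axis), at 3, 9 and 15 h, with IFN-γ in the top row and CpG in the bottom row. Coloured points are called in both comparisons and lie in the lower left or upper right corner, the dotted line marks equal change, and r across enhancers runs from 0.52 to 0.62 for IFN-γ and from 0.33 to 0.43 for CpG.

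A smaller set of enhancers was higher with both stimuli than with either one at the same time. It held 11 enhancers at 3 h, 21 at 9 h and 16 at 15 h, and a further 2, 10 and 4 were lower than with either. Members given below were chosen after their values were seen. The enhancer chr16:17285443-17285962 had 44 and 32 tags with both stimuli at 9 h, 4 and 8 with IFN-γ, 0 and 1 with CpG and none in unstimulated cells, a log2 difference of 2.86 ± 0.45 from IFN-γ (SE; edgeR adjusted p = 2.33e-07). Enhancer chr4:132459018-132459199 was above both at all 3 times, at 1.94 ± 0.276 RPM at 9 h against 0.326 ± 0.155 with IFN-γ and 0.186 ± 0.158 with CpG, with log2 differences of 2.70 ± 0.51 and 3.58 ± 0.58 (edgeR adjusted p = 7.45e-05 and 2.37e-07). At 3 h its call against IFN-γ was lost with any 1 of the 4 libraries left out, and at 15 h without either IFN-γ library or combination replicate 1. At 15 h the call against CpG was also lost without CpG replicate 2 or combination replicate 1. Enhancer chr5:121537641-121537963 had 57 and 47 tags with both stimuli at 9 h against 25 and 22 with IFN-γ and 6 and 7 with CpG, log2 differences of 1.35 ± 0.32 and 3.26 ± 0.40, and was above both again at 15 h. Without IFN-γ 9 h replicate 2 its call against IFN-γ at 9 h was lost. Enhancer chr3:79078776-79079153 had 26 and 20 tags at 9 h against 3 and 0 with IFN-γ and 0 and 4 with CpG, and chr13:33186931-33187283 had 41 and 37 at 15 h against 7 and 7 and 10 and 8.

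Among the enhancers below both single stimuli, chr5:34684166-34684741 had 90 and 91 tags in unstimulated cells, 32 and 40 with IFN-γ at 15 h, 31 and 21 with CpG and 9 and 9 with both, log2 differences of -2.38 ± 0.39 and -1.72 ± 0.41 (SE; edgeR adjusted p = 7.74e-07 and 0.00298). The second was lost without CpG 15 h replicate 1 or combination 15 h replicate 2. The numbers below both were 0 to 2, 0 to 5 and 0 to 3 at 3, 9 and 15 h with 1 library left out, 0, 1 and 1 with DESeq2, and 0, 10 and 3 with whole-library totals. The numbers above both were 0 to 6, 7 to 10 and 5 to 9 at 3, 9 and 15 h with 1 library left out, 0, 5 and 4 with DESeq2, and 46, 9 and 21 with whole-library totals.

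**Figure D3:**
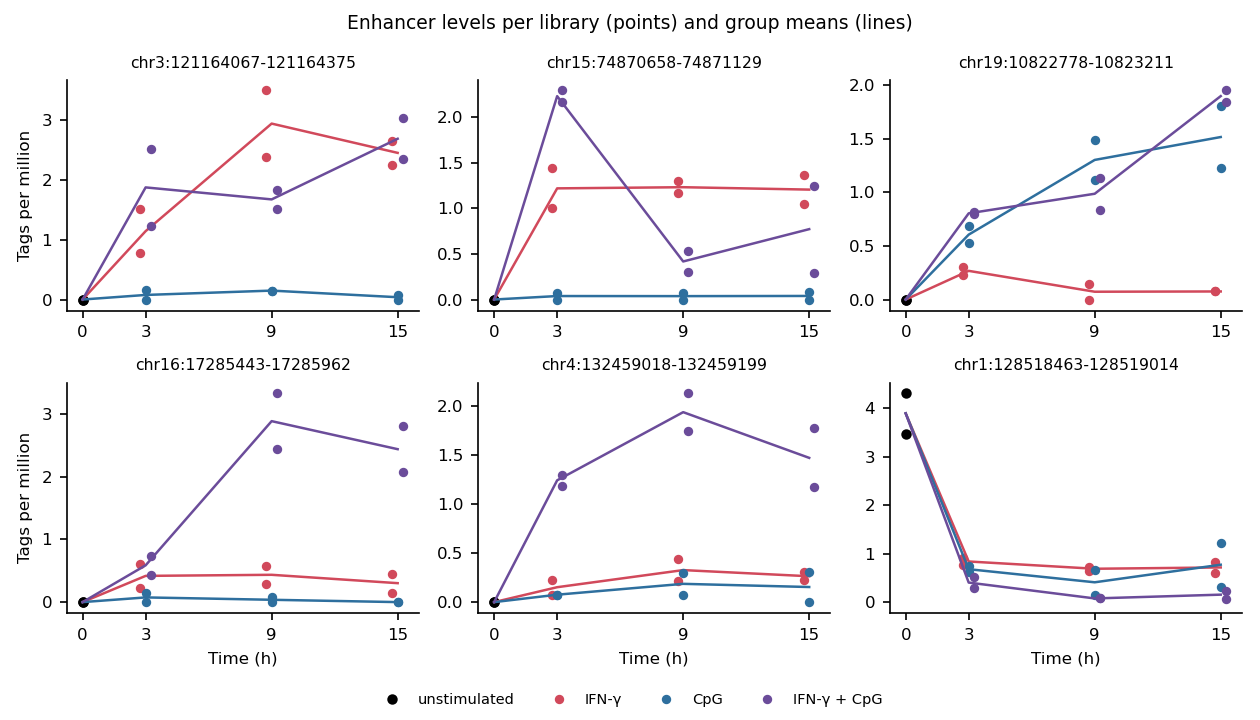
RPM (tags relative to the whole library) of 6 enhancers in each library (points) with the mean of the 2 libraries of a group (lines), from unstimulated cells at 0 h to 15 h. The enhancers were picked after their values were seen: chr3:121164067-121164375 and chr15:74870658-74871129 rose with IFN-γ, chr19:10822778-10823211 with CpG, chr16:17285443-17285962 and chr4:132459018-132459199 above all with both, and chr1:128518463-128519014 fell from 3.89 RPM with each stimulus.

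Called enhancers were not spread evenly over the genome. Windows of 1 Mb with at least 3 tested enhancers were tested for an excess of calls, for each comparison and direction with at least 20 calls, by a one-sided hypergeometric test adjusted within each of 34 families, and 39 of 13974 tests passed. This test was added after the data had been seen, and neighbouring enhancers were treated as independent. Excesses of a window in comparisons that share libraries are not separate support, and windows were not retested with a library left out. On chromosome 15, 74 to 75 Mb, 8 of 8 tested enhancers were higher with IFN-γ at 9 h where 1.03 would be by chance (adjusted p = 2.87e-05), and 6 of 8 at 15 h (0.00975). With CpG against IFN-γ at 9 h all 8 were lower (1.89e-05). On chromosome 17, 34 to 35 Mb, 6 of 7 were lower with CpG than with IFN-γ at 15 h against 0.692 by chance (adjusted p = 0.00234), a window not past the threshold when shifted by 0.5 Mb or changed in size to 0.5 or 2 Mb. On chromosome 5, 91 to 92 Mb, 5 of 5 were higher with CpG than with IFN-γ at 9 h against 0.484 by chance (0.00336), and on chromosome 5, 100 to 101 Mb, 5 of 5 were higher with IFN-γ at 9 h against 0.643 (0.00705).

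Rises with CpG were clustered on chromosome 4, 62 to 63 Mb: 5 of 7 enhancers were higher with CpG at 15 h against 0.318 by chance (adjusted p = 0.00145). Falls were clustered on chromosome 8, 84 to 85 Mb: 9 of 11 tested enhancers were lower with both stimuli at 15 h against 1.06 by chance (adjusted p = 1.24e-05), 6 of 11 at 9 h (0.0401) and 5 of 11 with IFN-γ at 3 h (0.00301). All of these comparisons share the unstimulated libraries. The excess at 9 h and that with IFN-γ at 3 h were found again with windows of 2 Mb and not with windows of 0.5 Mb or shifted ones. On chromosome 2, 13 to 14 Mb, 5 of 7 were lower with both stimuli at 15 h against 0.677 by chance (0.0299) and 4 of 7 with IFN-γ at 15 h (0.0244), the latter found again with 2 Mb alone. On chromosome 1, 173 to 174 Mb, 6 of 7 were higher with both stimuli than with CpG at 3 h against 0.797 by chance (0.00544), which was not found with 2 Mb. On chromosome 8, 47 to 48 Mb, 7 of 9 were higher with both stimuli at 9 h against 1.27 (0.0119).

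**Figure D4:**
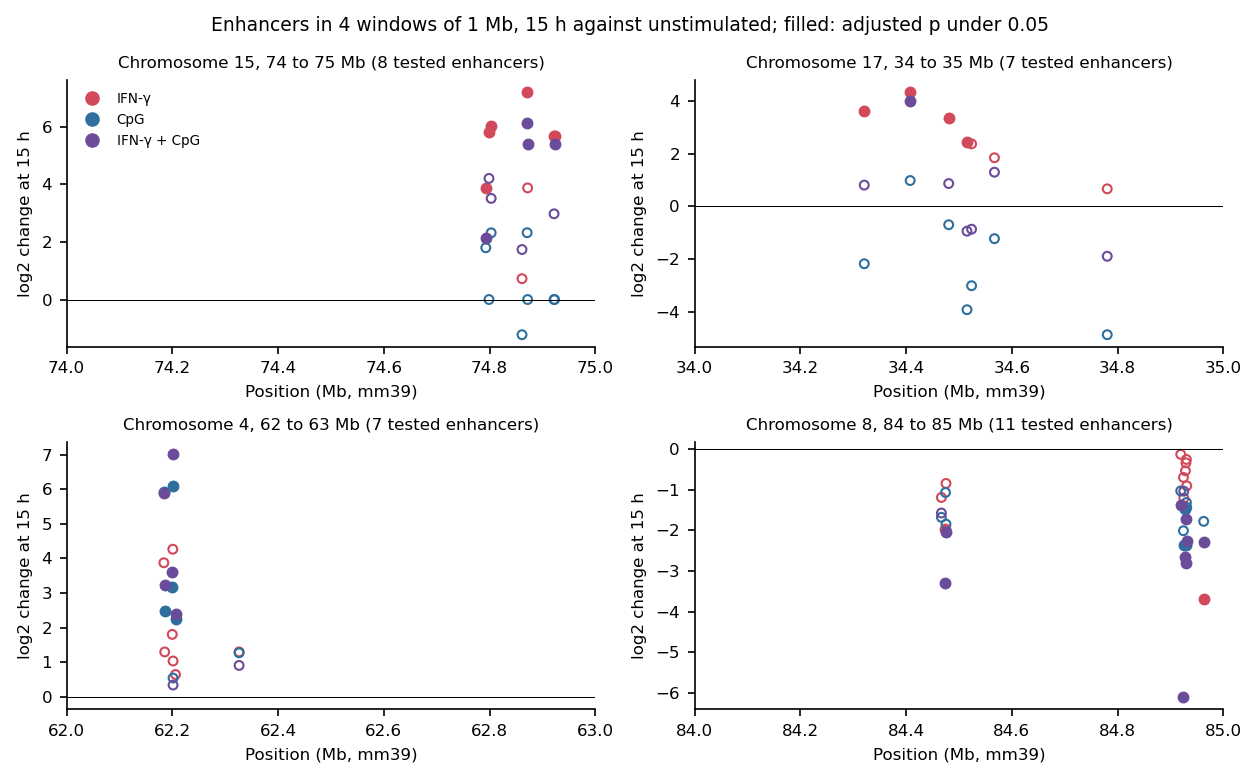
Log2 change at 15 h against unstimulated cells for the tested enhancers of 4 windows of 1 Mb, by position on mm39, for IFN-γ, CpG and both stimuli, with filled points for an edgeR adjusted p under 0.05. In the window on chromosome 15, 6 of 8 enhancers were called higher with IFN-γ, in that on chromosome 4, 5 of 7 with CpG, and in that on chromosome 8, 9 of 11 were called lower with both stimuli; changes of enhancers with 0 tags in a group depend on the prior count.

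Early and late levels with the same stimulus were compared at 15 h against 3 h, where both groups are treated and time with the stimulus and time in culture differ together. With CpG 18 enhancers differed (8 higher, 10 lower), with IFN-γ 29 (11 higher, 18 lower) and with both stimuli 259 (125 higher, 134 lower). These counts were not compared at equal depth: IFN-γ 3 h replicate 2 held 8138 tags in tested enhancers and combination 3 h replicate 2 held 17573. The enhancer at chr19:11349540-11350041 rose with CpG from 0.490 ± 0.153 to 4.81 ± 0.0477 RPM, a log2 change of 3.07 ± 0.39 (SE; edgeR adjusted p = 1.29e-11). It stood at 0.218 ± 0.203 in unstimulated cells and 0.226 ± 0.00170 with IFN-γ at 15 h. With both stimuli chr2:48584475-48584861 fell from 1.43 ± 0.178 to 0.0738 ± 0.104, 39 tags against 2, a ratio of 19.7-fold (95% counting interval 5.09 to 168), and chr6:82741188-82741493 from 26 tags to 1, a ratio of 26.2-fold (95% counting interval 4.31 to 1076). Of the 4 enhancers with the largest changes for IFN-γ, none kept its call under DESeq2, which called 0, 1 and 53 enhancers for IFN-γ, CpG and both stimuli. Leaving out 1 library gave 1 to 14, 2 to 8 and 79 to 130 calls; the share of rises for CpG was 44.4%, and 72.7% of 11 calls with whole-library totals. For IFN-γ it was 37.9%, and 48.6% with RLE factors. Which direction had more calls changed between settings for each of the 3 stimuli, for both stimuli from 125 higher and 134 lower to 109 and 92 with whole-library totals and 64 and 21 without combination 15 h replicate 2.

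The last comparison asked whether the log2 response to both stimuli differed from the sum of the single responses. Few enhancers passed this test: 1 at 3 h, 0 at 9 h and 3 at 15 h with edgeR, where 189, 272 and 278 had an unadjusted p under 0.05 against 139.6 by chance, while DESeq2 called 0 at each time and limma 47, 2 and 34. At 3 h chr17:27766195-27766562 fell short of the sum by a log2 value of -2.67 ± 0.62 (SE; edgeR adjusted p = 0.0460), a call lost under 14 alternatives, library totals and the replicate block among them. At 15 h chr17:26733530-26734046 lay above the sum by 4.02 ± 0.80 (edgeR adjusted p = 0.00127): it stood at 2.17 ± 0.615 RPM in unstimulated cells, 0.264 ± 0.162 with IFN-γ, 0.310 ± 0.106 with CpG and 0.925 ± 0.787 with both. Its call was lost without IFN-γ 15 h replicate 2 or combination 15 h replicate 2. On simulated data of the same depth this test found 30% of 8-fold and 8.00% of 4-fold departures at 9 h, so that most departures of this size were not detectable.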

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

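The test of the share of rises by level in either group compared, the tests by whole-library totals, and the tests of both stimuli at 9 h, were chosen after the results they bear on had been seen, as were the medians over enhancers with more than 3 tags in each group. The other tests in this part were written down after the counts of calls were known and before the tests were run.

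Enhancers that differed between 15 h and 3 h of the same stimulus numbered 29 for IFN-γ, 18 for CpG and 259 for both stimuli, by an edgeR test of the difference itself. This difference also contains any effect of time in culture. Departures from additivity singled out chr17:27766195-27766562 at 3 h (log2 -2.67, adjusted p = 0.0460), and at 15 h chr17:10921669-10922252 (5.42, 0.0128), chr17:26733530-26734046 (4.02, 0.00127) and chr2:167217104-167217506 (6.26, 0.0128). The values for chr17:10921669-10922252 and chr2:167217104-167217506 rest on 1 tag in the CpG group at 15 h, so that their sizes depend on the prior count.

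More enhancers were called for both stimuli against unstimulated cells than for either alone, 764 against 293 at 3 h, 624 against 543 at 9 h and 705 against 420 at 15 h. Such a gap is not a number of enhancers that differ between the stimuli. Tested directly against IFN-γ, both stimuli differed at 36 enhancers at 3 h (1 with DESeq2), 180 at 9 h and 256 at 15 h. Depth is argued against at 3 and 15 h: after every library was thinned to 8138 tags in tested enhancers, the ratio of calls over the larger single stimulus had a median of 2.37 at 3 h (2.07 to 2.78 over 10 draws) and 1.66 at 15 h (1.55 to 1.87), where a ratio above 1.5 in each draw had been set for excluding it. Scaling as the whole cause is argued against by the same bound, since with whole-library totals on the thinned libraries the ratio was 2.40 at 3 h (1.98 to 2.55) and 1.87 at 15 h (1.64 to 2.04). At 9 h the ratio of 1.15 rose with thinning, to 1.35 with TMM (1.3 to 1.52) and 1.51 with whole-library totals (1.38 to 1.75). The libraries of both stimuli held 11529 and 10870 tags in tested enhancers at 9 h, and those of IFN-γ 10894 and 14993, so that both stimuli had no clear advantage in depth there. Thinning could therefore hardly lower the ratio, and no conclusion on depth or scaling is drawn from it at 9 h. A contribution of CpG on top of IFN-γ may account for part of the difference at 3 h: the 33 enhancers that rose with CpG alone had a median log2 change of 1.61 in both stimuli against IFN-γ, in other libraries, and 1.07 over the 14 with more than 3 tags in each group. Of these 33, 2 were called higher in that comparison.

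With CpG 43 enhancers were called at 3 h and 195 at 9 h, against 68 and 132 with the stricter filter, 20 and 41 with DESeq2 and 111 and 287 with limma. In edgeR with the main filter, depth as the whole cause is argued against. The ratio after thinning had a median of 3.4 (2.45 to 4.4 over 10 draws), where a ratio above 2 in each draw had been set for excluding depth. Scaling as the whole cause is argued against by the same bound, with a ratio of 5.46 (4 to 7.5) with whole-library totals on the thinned libraries. Thinning was not run with the stricter filter, DESeq2 or limma, where the counts differed by a smaller factor. No conclusion on depth or scaling covers these settings. A response that builds up after 3 h is a candidate explanation: the 125 enhancers that rose at 9 h had a median log2 change of 0.72 in CpG at 15 h against 3 h, from other libraries, and 0.53 over the 90 with more than 3 tags in each group. Time in culture without a stimulus was not tested and stays open.

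In each comparison with unstimulated cells rises outnumbered falls under TMM. Because the enhancer regions may have been called on libraries of which most are stimulated, rises were counted among the upper quartile of enhancers by mean tags, where they made up a median of 62.9% of calls (60.6% to 75%), which met the bound of 60% that had been set for excluding this explanation. That bound does not decide, because ranking by the mean over libraries that are mostly stimulated itself favours rises; ranked by the higher level of the groups compared, the median was 59.4% (52.4% to 75.7%). With whole-library totals the median share of rises over all calls was 55.2% (42.0% to 70.8%). With limma, which was run on RPM and so shares this scaling, falls outnumbered rises in 5 of the 9 comparisons. In simulated data for IFN-γ at 3 h, the test found 12.0% of 4-fold falls and 50.0% of 4-fold rises. All groups started there from the same mean level, so that the falls had fewer tags than the rises. A fall over the same levels as a rise was not simulated. Equal numbers of true rises and falls from equal starting levels could thus give more called rises. Whether real rises and falls started from equal levels was not tested. Region calling, scaling and this difference in detection cannot be told apart from a true excess of rises, since no measure independent of the enhancer set and its scaling was at hand.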

How the results depend on the processing

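The thinning to equal tags, whole-library totals on thinned libraries and for additivity, the window sizes and the count above both stimuli were alternatives or results chosen after seeing the data; the others were planned. Of 1303 fits of the 131 named values under alternatives other than leaving out a library, 1217 kept the call, 86 lost it and 0 reversed; when a library was left out, 417 of 532 kept it and 115 lost it. Losses of named values were 27 of 131 with DESeq2, 24 with limma plus 2, 18 without a filter and 0 to 8 with each other setting. Named values had the largest changes, and other calls can hold less often. For IFN-γ at 3 h against unstimulated cells, DESeq2 shared 88 of the 293 main calls. The planned gene list and motif tests and their alternatives were not run, since no annotation or genome of the build was used here. With 1 library left out, a group has a single library that is assumed to vary like the other groups. The median of 3 tags per tested enhancer and library limits what can be called: in simulated data for IFN-γ at 3 h, 12.0% of 4-fold falls and 50.0% of 4-fold rises were found. Pairing of samples by replicate number was not seen: over 45 pairs of groups the deviations of replicate 1 correlated at -0.051 to 0.038. Replicates differed by little more than counting noise (chi-square per degree of freedom 1.1 to 1.28), so that this check cannot exclude a pairing. With the replicate block 280, 521 and 402 enhancers were called for IFN-γ at 3, 9 and 15 h. Of the counts, the block moved by more than 1.5 times the departures from additivity at 3 h, from 1 to 0, and no other. The block also ended the call of 5 enhancers above or below both single stimuli. The lower counts after thinning follow from fewer tags. Without a filter more enhancers were tested, and the factors and the spread were fitted anew. For this and the other alternatives the cause was not tested. Window tests past the threshold numbered 39, and 31, 27 and 29 with windows of 0.5 Mb, of 2 Mb and shifted. The same window could pass in several comparisons, so that distinct windows were fewer.

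Counts of calls that moved by more than 1.5 times are given in the order 3, 9 and 15 h where all times moved. With DESeq2 they were 88, 159 and 120 for IFN-γ, 20, 41 and 46 for CpG and 271, 211 and 233 for both stimuli against unstimulated cells. Between stimuli DESeq2 called 1, 28 and 55 for both against IFN-γ, 118, 56 and 36 for both against CpG, 78, 180 and 137 for CpG against IFN-γ. It called 0 at 3 h and 0 at 15 h for departures from additivity, 0, 1 and 53 for 15 h against 3 h with IFN-γ, CpG and both, and 0, 5 and 4 above both single stimuli. Without a filter they were 140, 315 and 208 for IFN-γ, 19, 74 and 85 for CpG and 394 for both stimuli at 9 h. Between stimuli they were 4, 68 and 103 for both against IFN-γ, 270, 67 and 65 for both against CpG, 132, 382 and 250 for CpG against IFN-γ. The others were 0 departures at 3 h, 9, 7 and 113 for 15 h against 3 h, and 1, 7 and 10 above both.

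With the stricter filter they were 266 and 232 for IFN-γ at 9 and 15 h, 68 for CpG at 3 h and 352, 314 and 316 for both stimuli. They were 265 for both against CpG at 3 h, 326 and 275 for CpG against IFN-γ at 9 and 15 h, 8 departures at 15 h and 43 for CpG at 15 h against 3 h. With whole-library totals they were 110 for both against IFN-γ at 3 h, 0 departures at 3 h and 6 at 15 h, 16 and 11 for 15 h against 3 h with IFN-γ and CpG, and 46 and 9 above both at 3 and 9 h. With limma they were 111 for CpG at 3 h, 263, 278 and 479 for both against IFN-γ, and 284 and 247 for both against CpG at 9 and 15 h. They were 47, 2 and 34 departures, 73, 67 and 458 for 15 h against 3 h, and 159, 32 and 76 above both. Fits of the compared groups alone gave 78 for CpG at 3 h and 35 for CpG at 15 h against 3 h, and RLE factors 0 departures at 3 h. Thinning gave medians of 144, 241.5 and 186 for IFN-γ, 15, 49 and 65 for CpG and 343, 325 and 325 for both.

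With 1 library left out, counts ranged over 99 to 162, 228 to 369 and 137 to 195 for IFN-γ, 11 to 22, 52 to 86 and 59 to 95 for CpG and 382 to 510, 294 to 372 and 336 to 483 for both stimuli. Between stimuli they were 1 to 4, 42 to 59 and 74 to 105 for both against IFN-γ, 161 to 275, 49 to 71 and 33 to 72 for both against CpG and 97 to 123, 234 to 392 and 207 to 231 for CpG against IFN-γ. They were 0 to 1, 0 to 1 and 0 to 4 for departures from additivity, 1 to 14, 2 to 8 and 79 to 130 for 15 h against 3 h with IFN-γ, CpG and both, and 0 to 6, 7 to 10 and 5 to 9 above both.

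Counts below both single stimuli, 2, 10 and 4, moved to 0, 1 and 1 with DESeq2, to 0, 2 and 1 without a filter, to 6 and 9 at 3 and 15 h with the stricter filter, to 0 and 2 at these times with limma, and to 0 at 3 h with whole-library totals. Rises shared by a stimulus alone and on top of the other, 141, 81 and 52 for IFN-γ and 2, 42 and 53 for CpG, moved with DESeq2 to 41, 32 and 23 and to 0, 7 and 14. Without a filter they were 63, 35 and 27 for IFN-γ and 0, 15 and 22 for CpG. For CpG at 3 h they were 4 with RLE factors, 7 with whole-library totals, 9 with the stricter filter and 9 with limma, and at 9 h they were 26 with whole-library totals.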

Other observations

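The test in this part was written down before it was run, and the medians over members with more than 3 tags were added after its result was seen, as were the values with whole-library totals. Single departures from additivity were few, but as a set the enhancers that answered IFN-γ may respond less than additively at 9 and 15 h when CpG is present, relative to other enhancers. Taking enhancers raised by IFN-γ on average over the absence and presence of CpG, a choice meant not to favour either direction of the departure, and TMM factors, the median departure was 0.0358 at 3 h (486 enhancers), -0.80 at 9 h (419) and -0.93 at 15 h (382), against 0.03, -0.01 and 0.10 for the other tested enhancers. The choice does not guard against time in culture, since unstimulated cells were taken at 0 h alone. A rise with time in culture would enter the choice and, with the opposite sign, the departure, and so favour negative values. At 9 h 69.0% and at 15 h 69.9% of the set lay below 0. Against the other enhancers camera gave p = 9.82e-05 and 1.04e-06 with a preset correlation and p = 0.00184 and 1.04e-04 with an estimated correlation, and at 3 h p = 0.882 and p = 0.853. Fitted values with 0 tags in a group depend on the prior count: over the 77, 70 and 56 members with more than 3 tags in each group the medians were -0.19, -0.48 and -0.51, against -0.14, 0.09 and -0.03 for other enhancers. The corresponding sets for CpG had medians of -0.13, 0.00 and 0.34 and were not set apart (p = 0.487, 0.885 and 0.154 with an estimated correlation). With whole-library totals the medians of the IFN-γ sets were 0.69, -0.93 and -0.48, against 0.74, -0.12 and 0.57 for other enhancers, and p with an estimated correlation was 0.911, 0.135 and 0.0555, or 0.925, 0.126 and 0.0457 for sets also chosen with these totals. Over members with more than 3 tags in each group they were then 0.55, -0.60 and -0.02, against 0.61, -0.02 and 0.47. The difference from other enhancers at 9 and 15 h thus had the same sign with both scalings, while its p depended on the scaling. At 15 h the median departure over members with more than 3 tags was near 0 with whole-library totals, and the hypothesis stays open for 9 and 15 h. At 3 h the IFN-γ set was not set apart from other enhancers with either scaling.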
